A study of Mus musculus with 4 samples.

How the data were processed

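Single-cell RNA libraries of mouse rostral neocortex at E15.5 were analysed, 2 from i4F-Nes embryos and 2 from littermate control (CTR) embryos. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cortical tissue was dissociated with papain and captured with the 10x Genomics Chromium Next GEM 3′ v3.1 chemistry. The deposited matrices held whole-number UMI counts per gene and barcode, 1 matrix per library with no pooling of replicates, and per the file headers the authors made these counts with cellranger 7.0.1. The genome build was mm10, per the submitters' processing notes. The annotation release, the counting of intronic reads, the number of embryos per library and any removal of doublets or free RNA are not given in the sources used here. Each matrix listed 32285 genes with gene identifiers and symbols, which were used as given. Coordinates of named genes were taken from GENCODE M21 on GRCm38, the assembly behind mm10, and all 197 named genes matched it by gene ID, 196 of them with the same symbol.

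The 4 matrices held 35255 barcodes and 458145772 UMIs. Barcodes were kept with at least 1000 UMIs, at least 500 detected genes and at most 10% of UMIs from mitochondrial genes, which left 28672. Doublets were scored per library with Scrublet as implemented in scanpy, and the barcodes with the highest scores were removed at 0.8% per 1000 barcodes, 2031 in all. Scrublet's automatic threshold would have marked 372 and 188 barcodes in i4F-Nes replicates 1 and 2 and 404 and 373 in CTR replicates 1 and 2. The comparisons used the remaining 26641 cells with 385501862 UMIs. The highest-expressed 10 genes took 5.81% to 6.52% of the UMIs of a library. Intervals on shares are exact binomial (Clopper-Pearson) 95% intervals, and a share of 0 is given, at its first mention, with the share that 3 counts would make. Both cover counting error only.

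Counts were log-normalised per cell. From the variable genes of each library, 2000 were combined, leaving out sex-linked, mitochondrial, ribosomal protein and haemoglobin genes. Clusters came from 30 principal components, 15 nearest neighbours and the Leiden algorithm at resolution 1.0 with seed 1 and no batch integration, which gave 27 clusters. Clusters were named from 16 marker lists covering radial glia, intermediate progenitors, immature, upper-layer, deep-layer and subplate neurons, interneurons, striatal or ganglionic eminence cells, Cajal-Retzius cells, oligodendrocyte precursors, endothelial and mural cells, microglia or macrophages, meningeal fibroblasts, erythroid cells, and choroid plexus or cortical hem cells. A name needed at least 3 markers detected in at least 10% of the cluster's cells and no surplus of another class's markers among the 10 leading genes. Clusters with over 75% of their cells from 1 library, over 98% from 1 group, or a median UMI count under the fraction 1/3 of their libraries' medians without own markers among the leading genes stayed numbered. The limits on library and group shares were set after the clusters were seen. Names were rebuilt here without an annotation by the authors, so a difference from the study may come from rebuilt names.

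UMI counts were summed per library over all kept cells and over each class with at least 20 cells in every library. They were tested with edgeR's quasi-likelihood F-test (TMM scaling, filterByExpr, robust fit, no covariates) and Benjamini-Hochberg adjustment at 0.05. DESeq2's Wald test was the other tool. Fold changes are log2 of i4F-Nes over CTR with the standard error of the fit, and levels are TMM-scaled CPM unless a cluster's own CPM is named. Where CTR held 0 counts the fold is a lower bound against 3 counts over the group, and with 1 to 3 CTR counts the ratio of summed counts is given with its counting interval. Numbers of cells per class were tested with edgeR's quasi-likelihood test with the kept cells as library size, no TMM and no dispersion trend, over 15 classes. The difference of response between radial glia-like and upper-layer neuron-like cells was tested as an interaction with the library as a block. The upper-layer share, the neuron to progenitor ratio and the cycling share were compared with an exact two-sided permutation test, whose smallest possible p with 2 against 2 libraries (6 splits) is 0.333. For shares of cells with a UMI, cells were thinned to 3800 UMIs and shallower cells were left out.

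22 gene lists with at least 4 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. They covered the reprogramming factors, pluripotency, S phase, G2 and M phase, neuronal differentiation and synapse, the Notch and Wnt pathways, outer radial glia, p53 targets, Myc targets, glycolysis and hypoxia, interferon response, immediate early and dissociation genes, the unfolded protein response, DNA methylation and Polycomb, rostral and caudal cortex patterning, medial cortex and hippocampus, sex-linked genes, cytosolic ribosomal proteins, nuclear oxidative phosphorylation and the mitochondrial genome. The group map, the designs, the lists, the markers, the naming rule for genes and the alternatives listed first below were fixed before the data were examined. The rule named, per comparison, genes past the threshold with both i4F-Nes values on one side of both CTR values and a mean of at least 10 CPM. It took the 10 with the largest fold change per direction for all kept cells and for the class with most calls, and up to 5 for other classes. Where fewer than 10 passed it also took the 10 with the smallest p. It added the 4 factors, up to 4 members of each list that passed, and 10 state markers (Mki67, Top2a, Sox2, Pax6, Eomes, Neurod1, Cux2, Bcl11b, Tbr1 and 1 that is not reported here). Genes that describe clusters 10 and 12 and Fstl5 were named after their values were seen.

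The tests of genes, gene lists and class shares were tested on simulated data. Counts were drawn for the real genes with 200 genes changed by known folds. In all kept cells (18218 genes), 38% of 50 genes changed 2-fold and 96% of 50 changed 4-fold were called, with 34 false calls among 200. At 2-fold, 48% were called in radial glia-like cells (13278 genes), 46% in intermediate progenitor-like (13248), 62% in immature neuron-like (12952), 38% in upper-layer neuron-like (13938), 40% in deep-layer neuron-like (13478) and 24% in interneuron-like cells (9264). False calls there were 19 of 186, 19 of 191, 24 of 203, 17 of 179, 16 of 181 and 8 of 161, so the false share lay above the 5% aimed at in all but the last. The list test called the moved list in 7 of 7 simulations and the still list in 0, with either correlation. Genes were drawn independently of each other there. The simulations thus cannot show how often the preset correlation gives false calls for lists whose genes vary together. The test of class shares, at 8-fold in 20 draws of 12 classes, recovered 10 of 60 changed classes (16.7%) with 2 false calls, so it could miss large differences.

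Alternatives were DESeq2 size factors, no filter on low counts, DESeq2, sums thinned to the lowest total, no doublet removal, a stricter cell filter (2000 UMIs, 1000 genes, 5% mitochondrial), Leiden resolution 2.0, expression centred per library, each library left out in turn, the replicate number as a block, TMM over classes, unthinned shares, and for gene lists an estimated correlation and fry. Added after the data were seen were all kept cells without clusters 10 and 12 or without clusters 9 and 18, upper-layer cells with cluster 18, deep-layer cells with cluster 1, shares with other denominators, neuron measures with clusters 1 and 18, and clustering without the changed genes. Signatures of clusters 10 and 12 held 30 genes each, chosen in 1 i4F-Nes library among genes detected in at least 50% of the cluster's cells and sought in the other libraries as cells with 15 or more of them (10 or more where stated). Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1. Endothelial-like, mural-like, microglia- or macrophage-like and Cajal-Retzius-like cells were not among the classes listed for gene tests and were compared by share only.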

Results

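Transcriptomes of single cells from the rostral neocortex were compared at E15.5 between i4F-Nes embryos and littermate CTR embryos, with 2 libraries per group. i4F-Nes embryos carried a doxycycline-inducible cassette of the Yamanaka factors (Pou5f1, also called Oct4, Sox2, Klf4 and Myc), a Cre-dependent transactivator, and Nestin-Cre, which is active in neural progenitors. CTR embryos carried the cassette and the transactivator without the Cre. Pregnant females drank 0.2 mg/ml doxycycline for 4 days, from E10.5 to E14.5, so induction ended 1 day before collection. The i4F-Nes libraries held 9646 and 9457 barcodes with 153706503 and 94052724 UMIs, and the CTR libraries 7942 and 8210 barcodes with 113444320 and 96942225 UMIs. After filtering, 7498 and 6407 i4F-Nes cells and 6046 and 6690 CTR cells remained, with medians of 15162, 11320, 15132 and 11620 UMIs per cell. Replicate 1 of both groups was thus deeper than replicate 2. Xist, expressed from the inactive X chromosome, stood at 811 and 1030 CPM in i4F-Nes and at 0.0106 and 1200 CPM in CTR, and the Y-linked Ddx3y reached 42.4 CPM in CTR replicate 1 against at most 0.833 CPM elsewhere. The labels do not say whether libraries came from separate animals or litters, so p-values measure the spread between these samples, which may be partly technical. In fits with 1 library left out, 1 group held a single library, assumed to vary like the other group. Passing in such a fit is not taken as support for a gene that missed the threshold with all libraries.

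The reprogramming factors were examined first, as a check of the labels. Pou5f1, a core pluripotency transcription factor (ENSMUSG00000024406, GRCm38 chromosome 17, 35506018 to 35510772), was measured at 28.8 and 10.6 CPM over all kept i4F-Nes cells and at 1.93 and 1.33 CPM in CTR, a log2 fold change of 3.59 ± 0.553 (SE, n = 2 per group). Its adjusted p of 0.0503 in edgeR's test lay just outside the threshold of 0.05. It passed without i4F-Nes replicate 1 (2.69, adjusted p = 0.00305) and without i4F-Nes replicate 2 (4.16, adjusted p = 0.000158), and over its alternatives the adjusted p ran from 1.36e-13 to 1.00. Sox2, which also marks neural progenitors, stood at 82.5 and 74.7 CPM against 95.9 and 54.4 CPM (0.06 ± 0.273, adjusted p = 0.966). Klf4 differed by −0.31 ± 0.389 (adjusted p = 0.859) and Myc by −0.36 ± 0.306 (adjusted p = 0.776), and the sign of Sox2 turned without i4F-Nes replicate 1 (−0.01) or CTR replicate 2 (−0.27), that of Klf4 (0.32) and Myc (0.10) without CTR replicate 1. Of the 4 factors 0 passed over all genes tested in edgeR, and 1 passed when adjusted over the list alone. As a list they did not pass camera (adjusted p = 0.456, and adjusted p = 0.815 with an estimated correlation), and the median of −0.12 differed in sign from the mean of 0.75 and from the test's upward direction. A 3′ tag of the transgene may lie outside the annotated genes, so the absence of a difference checks nothing.

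The first comparison asked which cell populations differed in abundance after transient induction. Cells of clusters 10 and 12 were found almost exclusively in i4F-Nes libraries. Cluster 10 held 6.36% (5.82 to 6.94) and 7.74% (7.10 to 8.42) of kept i4F-Nes cells, a mean of 7.05% ± 0.976 (SD, n = 2), and 0 of 6046 and 0 of 6690 CTR cells, which allows CTR shares of up to 0.0496% and 0.0448%. Its share was at least 297-fold higher in i4F-Nes. Cluster 12 held 4.63% (4.16 to 5.13) and 7.12% (6.5 to 7.77) of i4F-Nes cells, a mean of 5.87% ± 1.76 (SD, n = 2), and 1 cell of CTR replicate 1 (0.0165%) and 0 of 6690 cells of CTR replicate 2 (up to 0.0448%), a ratio of 735 (95% counting interval 132 to 29086). Both passed edgeR's test on cell numbers (adjusted p = 0.00468 for each), and together they made up 12.9% ± 2.74 of the i4F-Nes cells. With the replicate number as a block, a pairing that no label gives, 0 of 15 classes passed. Clustering repeated without the 406 genes that changed over all kept cells, an alternative chosen after the data were seen, gave the same groups: 97.2% of cluster 10 fell into a cluster of 953 cells with 0 CTR cells, and 95.8% of cluster 12 into a cluster of 794 cells with 1 CTR cell. Against radial glia-like cells, 657 genes were at least 2-fold higher and 701 lower in cluster 10. Against immature neuron-like cells, 776 were higher and 290 lower in cluster 12. Many genes that set the clusters apart thus stayed in, and finding the groups again is no independent support.

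No other class passed among the 15 tested, and 2 had an unadjusted p under 0.05, the same clusters 10 and 12. Radial glia-like cells, the neural stem cells of the cortex, made up 10.6% ± 2.39 of i4F-Nes and 10.2% ± 3.58 of CTR cells (SD, n = 2 each; adjusted p = 0.975). Intermediate progenitor-like cells made up 9.72% ± 3.21 and 13.6% ± 3.45, immature neuron-like cells 12.9% ± 5.47 and 18.9% ± 3.90, and upper-layer neuron-like cells 18.9% ± 1.59 and 23.5% ± 5.03 (adjusted p = 0.901 for each). Deep-layer neuron-like cells made up 13.5% ± 2.33 and 13.7% ± 1.91 (adjusted p = 0.975). Interneuron-like cells, inhibitory neurons that enter the cortex from the ventral forebrain, stood at 1.80% and 1.67% in i4F-Nes and at 3.51% and 6.43% in CTR (ratio 0.345, unadjusted p = 0.0524 and adjusted p = 0.262 in edgeR). Cajal-Retzius-like, microglia- or macrophage-like, endothelial-like and mural-like cells each had a mean under 1% in both groups (adjusted p = 0.901 for each), although without i4F-Nes replicate 2 mural-like cells passed too, which made 3 classes. No cluster was named as subplate neuron, striatal or ganglionic eminence, oligodendrocyte precursor, meningeal fibroblast, erythroid, or choroid plexus or cortical hem cells. Clusters 1, 9 and 18 also stayed numbered, with 7.35%, 6.92% and 4.15% of i4F-Nes and 8.66%, 4.10% and 0.786% of CTR cells, and 82.4% of cluster 18 came from i4F-Nes replicate 2. Counted over cells outside clusters 10 and 12, an alternative chosen after the data were seen, 0 of 13 classes passed in edgeR and 0 had an unadjusted p under 0.05. With expression centred per library, which rebuilt the clusters, 6 of 19 classes passed, among them immature neuron-like cells (33 and 14 cells in i4F-Nes against 620 and 496 in CTR). Cells were then split by group, as in a cluster of 1239 and 788 i4F-Nes against 14 and 9 CTR cells.

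**Figure D1:**
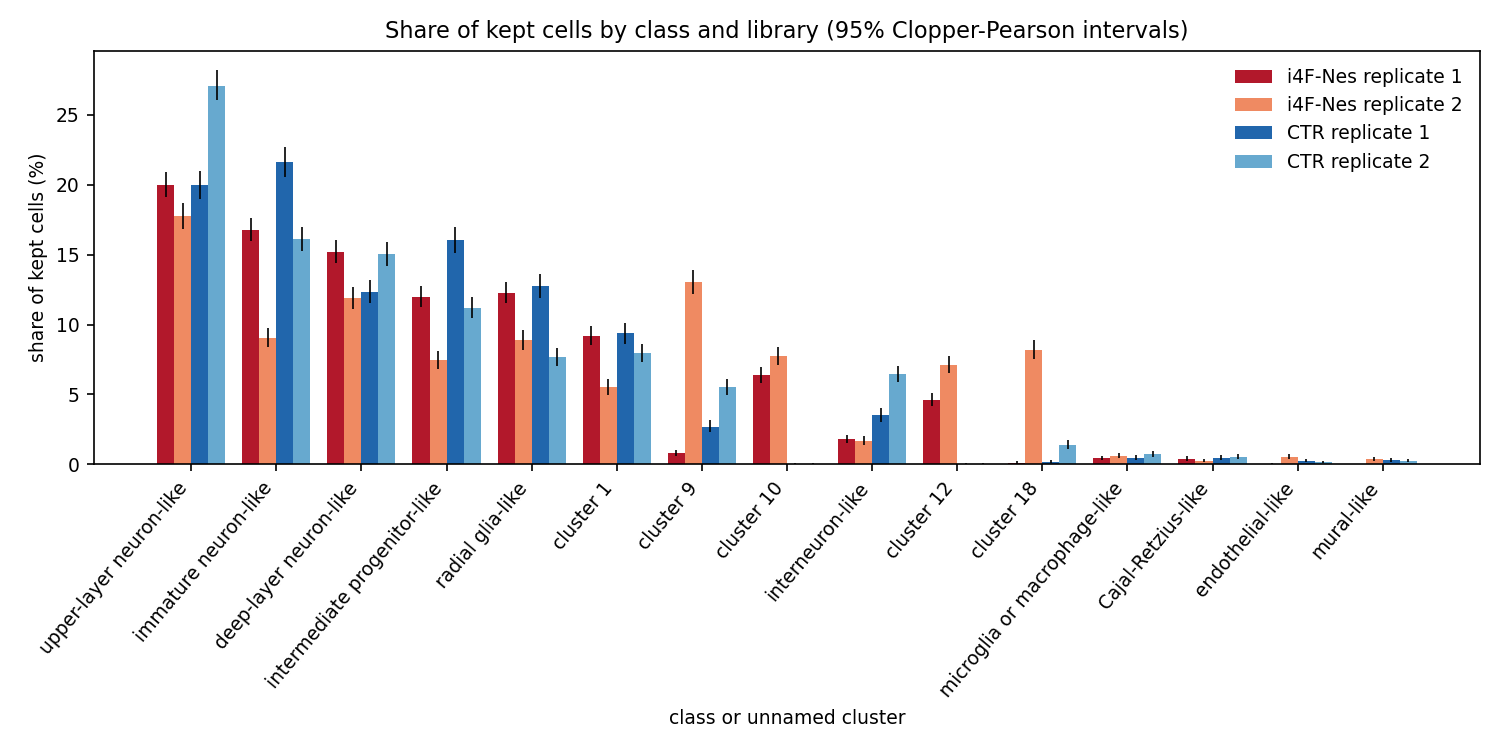
Bars show the percent of kept cells of each library in the 15 classes, with exact 95% binomial intervals, for the 2 i4F-Nes and 2 CTR libraries. Cluster 10 (6.36% and 7.74% against 0% and 0%) and cluster 12 (4.63% and 7.12% against 0.0165% and 0%) were the classes that passed the test.

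Cells of cluster 10 had a median of 34701 and 24264 UMIs in the i4F-Nes libraries, and their leading genes were Hopx, Crip1, S100a11, Lgals1, Cytl1, Tppp3, Cd109, S100a6, Lgals7 and Anxa1. Set against radial glia-like cells of the same libraries, as a description without a test, 0 of 17 radial glia markers were over 2-fold higher in both libraries and 13 were over 2-fold lower. Fabp7, a fatty acid-binding protein of radial glia, stood at 148 and 182 CPM against 5267 and 5098 CPM, and Sox2 at 148 and 188 against 466 and 379 CPM. Of 25 listed pluripotency genes 4 reached 10 CPM in both libraries, in cluster 10 or in radial glia-like cells, and these 4 were higher, among them Nanog, a transcription factor of the naive pluripotent state, at 109 and 39.3 CPM, and Epcam, an epithelial adhesion molecule, at 89.2 and 136.8 CPM. Other listed genes stayed near 0 in cluster 10, such as Zfp42 (0.982 and 0.0763 CPM), Esrrb (0.109 and 0), Dppa5a (0.218 and 0.382), Lin28a (0.164 and 0.0763) and Sall4 (1.91 and 1.83). Pou5f1 reached 176 and 50.8 CPM against 1.71 and 1.5 CPM. Of 43 S phase and 54 G2 and M phase genes, 0 were over 2-fold higher or lower. Markers of unlike cell types were higher too. They were 5 of 7 measured interneuron, 4 of 4 meningeal fibroblast and 2 of 3 oligodendrocyte precursor markers, with 0 lower in each list. After thinning, 25.8% and 9.69% of cluster 10 cells had a Nanog UMI (unthinned 72.1% and 35.5%) against 0.270% and 0% (up to 0.272%) of upper-layer neuron-like cells (unthinned 0.734% and 0.176%; medians 15078 and 14621 UMIs).

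Cells of cluster 12 had a median of 22370 and 15436 UMIs, and their leading genes were Krt8, Crabp2, Ebf1, Ebf2, Ebf3, Lgals7, Eya2, Tafa1, Thsd7a and Uncx. Set against immature neuron-like cells of the same libraries, again without a test, 8 of 12 listed Cajal-Retzius markers were over 2-fold higher in both libraries, such as the transcription factors Ebf2 (539 and 255 CPM) and Lhx1 (104 and 100.3 CPM). The other 4 did not reach 10 CPM in both libraries in either group of cells. Reln, the signalling protein that Cajal-Retzius cells secrete, stood at 3.93 and 9.57 CPM against 12.6 and 5.00 CPM. Of 21 listed interneuron markers 9 reached that level and 7 were higher, Sst, Npy and Nrxn3 among them. Gad2, an enzyme of GABA synthesis, stood at 1.6 and 4.93 CPM in cluster 12 against 707 and 636 CPM in interneuron-like cells, and Dlx1 at 0.123 and 0.145 against 165 and 178 CPM. Of 14 upper-layer markers 8 were lower and 0 higher. Pan-neuronal genes were present, with the tubulin Tubb3 at 2957 and 2724 CPM and the microtubule regulator Dcx at 581 and 725 CPM. Cdkn1a, the p53-regulated cell cycle inhibitor p21, reached 375 and 211 CPM in cluster 12 and 85.9 and 87.2 CPM in cluster 10, against 2.45 and 2.10 CPM in radial glia-like cells. After thinning, 49.4% and 31.4% of cluster 12 cells held a Cdkn1a UMI, against 0.643% and 1.34% of immature neuron-like cells. Unthinned shares were 70.3% and 45.4% against 2.70% and 2.93%.

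**Figure D2:**
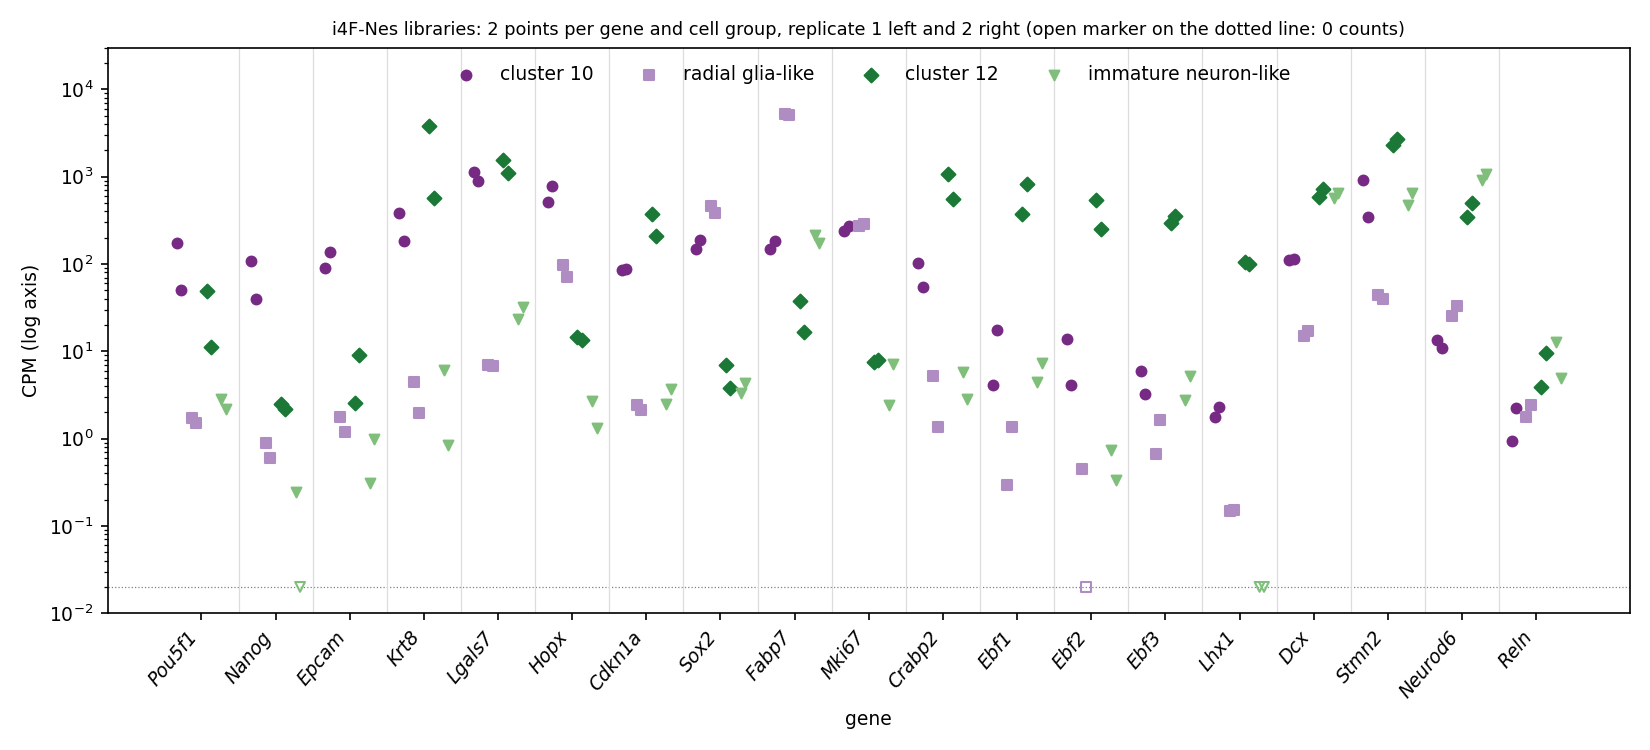
Points show CPM on a log axis for 19 genes in clusters 10 and 12 and in radial glia-like and immature neuron-like cells of both i4F-Nes libraries. Krt8 reached 3781 and 569 CPM in cluster 12, and Fabp7 fell from 5267 and 5098 CPM in radial glia-like cells to 148 and 182 CPM in cluster 10.

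Gene expression over all kept cells was compared next, which mixes composition with expression. Of 18556 genes tested, 406 were higher and 0 lower in i4F-Nes (edgeR; 2329 genes at an unadjusted p under 0.05). DESeq2 called 1173 genes, 1112 of them higher. Among genes with a mean of at least 10 CPM, the largest differences were in Krt8, an epithelial keratin (ENSMUSG00000049382, GRCm38 chromosome 15, 101996698 to 102004482), at 286 and 80.6 CPM against 0.0319 and 0.0253 CPM (log2 fold change 12.57 ± 1.06, SE, n = 2 per group, adjusted p = 0.0131), Cytl1, a secreted cytokine-like protein (ENSMUSG00000062329, chromosome 5, 37735519 to 37739820), at 28.6 and 33.8 against 0 and 0.0127 CPM (6535 against 1 count, ratio 5281, 948 to 208640, adjusted p = 0.00465), and Lbhd2 (ENSMUSG00000087075, chromosome 12, 111406809 to 111412090; 5877 against 3 counts, ratio 1583, 541 to 7679, adjusted p = 0.00630). They were followed by Anxa1, a phospholipid-binding annexin (8.25 ± 0.608), Crabp2, a retinoic acid-binding protein (6.43 ± 0.249, 83.6 and 60.6 against 0.892 and 0.773 CPM), Cd109 (6.17 ± 0.435), the metalloproteinase inhibitor Timp1 (6.04 ± 0.476), the small heat shock protein Hspb1 (5.85 ± 0.534), the galectin Lgals7 (5.26 ± 0.155) and the transcriptional cofactor Eya2 (5.24 ± 0.235), with adjusted p from 0.00465 to 0.0163. Mki67, a marker of cycling cells, rose by 1.11 ± 0.127 (adjusted p = 0.0242), while Top2a, a topoisomerase of dividing cells, did not pass (0.97 ± 0.180, adjusted p = 0.0764). Top2a passed without i4F-Nes replicate 1 (0.00625) or CTR replicate 1 (0.0198), in DESeq2 (0.000249), without a filter on low counts (0.0150) and without doublet removal (0.0333; range over alternatives 0.000249 to 1.00). Pax6 (−0.07), Eomes (−0.47), Neurod1 (−0.41), Cux2 (−0.34), Bcl11b (−0.15) and Tbr1 (−0.19), markers of cortical progenitors and neurons, did not pass. Without clusters 10 and 12, an alternative chosen after the data were seen, 0 genes passed in edgeR (337 at an unadjusted p under 0.05), and Crabp2 differed by 2.57 (adjusted p = 1.00; range over alternatives 3.23e-123 to 1.00). Leaving out i4F-Nes replicate 1, CTR replicate 1 or i4F-Nes replicate 2 gave 715, 779 and 626 genes, and Krt8 missed the threshold without CTR replicate 1 (adjusted p = 0.542) or CTR replicate 2 (adjusted p = 0.591; range over alternatives 6.85e-25 to 1.00).

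**Figure D3:**
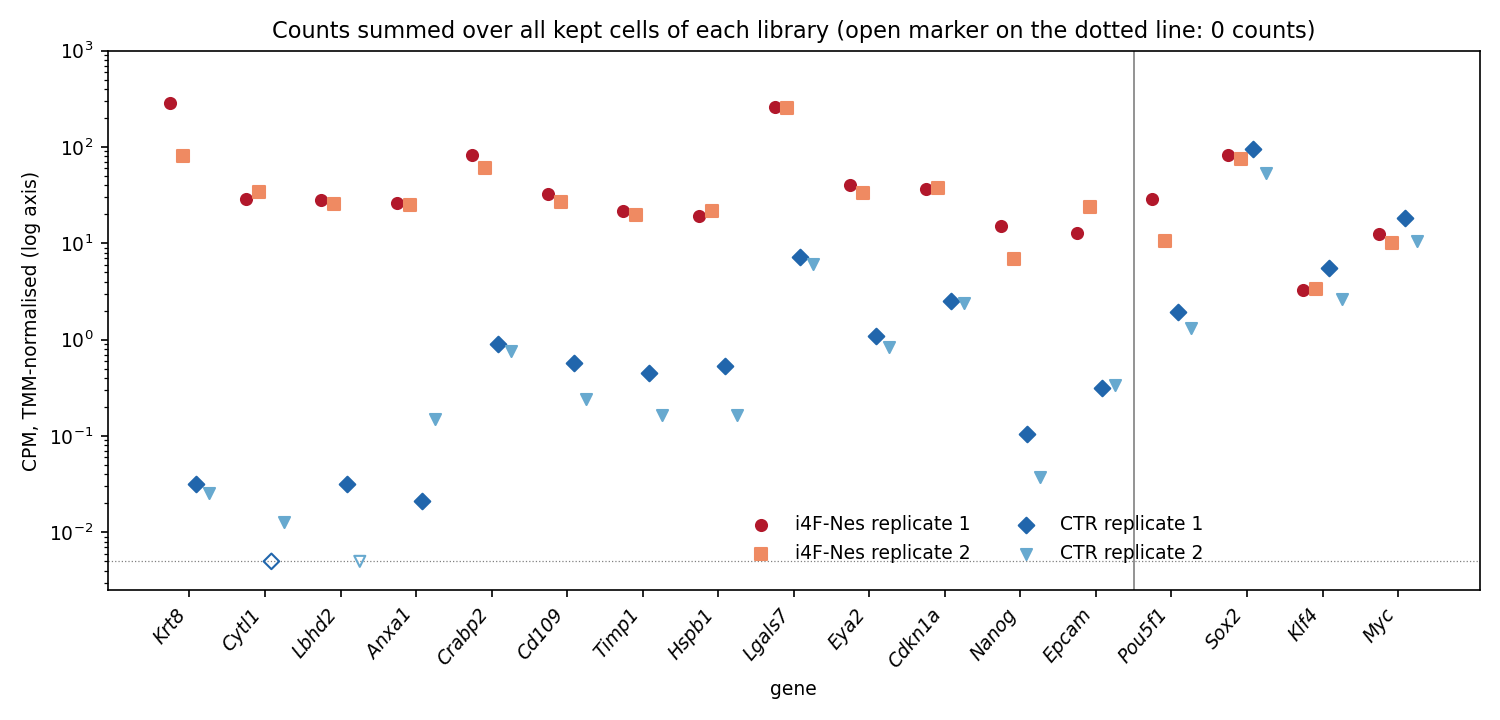
Points show TMM-scaled CPM over all kept cells on a log axis for 17 genes in the 4 libraries, with open markers on the dotted line for 0 counts. Krt8 stood at 286 and 80.6 CPM in i4F-Nes and at 0.0319 and 0.0253 CPM in CTR, while Sox2 lay at 82.5 and 74.7 against 95.9 and 54.4 CPM.

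Of the 22 gene lists, 11 passed over all kept cells. Pluripotency genes moved up as a list (adjusted p = 4.12e-13, and adjusted p = 0.319 with an estimated correlation), with 5 of 16 members higher and 9 when adjusted over the list alone. They included Nanog (ENSMUSG00000012396, GRCm38 chromosome 6, 122707489 to 122714633; 7.19 ± 0.674, adjusted p = 0.0174), Epcam (5.78 ± 0.415) and the signalling factor Gdf3 (322 against 3 counts, ratio 86.7, 29.4 to 423). G2 and M phase genes moved up (adjusted p = 1.16e-11, and adjusted p = 0.801 with an estimated correlation), with 1 of 54 passing and 18 adjusted over the list alone, and S phase genes moved up with 43 of 43 positive and 0 passing either way (adjusted p = 2.03e-05, and adjusted p = 0.815 with an estimated correlation). p53 targets moved up (adjusted p = 0.000960, and adjusted p = 0.434 with an estimated correlation), with 3 of 29 passing and 4 adjusted over the list alone: Cdkn1a (3.91 ± 0.157), the pro-apoptotic Pmaip1 (3.68) and the death receptor Fas (2.96). Fas missed the threshold without CTR replicate 1 (2.69, adjusted p = 0.0531; range over alternatives 0.000489 to 1.00). Outer radial glia genes moved up with 3 of 15 passing and 4 adjusted over the list alone, Hopx (2.65) and Fam107a (5.34) among them (adjusted p = 0.00216, and adjusted p = 0.434 with an estimated correlation). Without clusters 10 and 12, the first of which Hopx leads, an alternative chosen after the data were seen, Hopx turned to −0.32 and Itgb5 to −0.58. In cluster 10 itself, 4 of 12 measured members of the list were at least 2-fold higher than in radial glia-like cells and 6 were lower. Rostral patterning genes moved up with 1 of 10 passing and 5 adjusted over the list alone (adjusted p = 0.000500, and adjusted p = 0.434 with an estimated correlation). The member that passed was Etv5, a target of FGF signalling (1.14), which missed the threshold without i4F-Nes replicate 1 (1.07, adjusted p = 0.0811; range over alternatives 5.36e-07 to 1.00). Leaving out i4F-Nes replicate 1 left 7 lists.

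Immediate early and dissociation genes moved up over all kept cells (adjusted p = 0.0131, and adjusted p = 0.815 with an estimated correlation), with 4 of 31 passing and 5 adjusted over the list alone, such as Egr2 (2.53) and Nr4a1 (2.18). Without clusters 10 and 12, an alternative chosen after the data were seen, Egr2 turned to −1.62 and Egr1 to −0.25, and Nr4a1 stood at 0.29 (adjusted p = 1.00 for each). A further member, Zfp36 (1.55, adjusted p = 0.0477), missed the threshold without i4F-Nes replicate 1, CTR replicate 1 or i4F-Nes replicate 2 (adjusted p = 0.0626, 0.0544 and 0.109; range over alternatives 9.32e-07 to 1.00). Interferon response genes moved up with 1 of 18 passing, Ifitm3 (2.92), and 2 adjusted over the list alone (adjusted p = 0.0355, and adjusted p = 0.547 with an estimated correlation). Neuronal differentiation and synapse genes moved down with 34 of 38 negative and 0 passing either way (adjusted p = 0.00238, and adjusted p = 0.801 with an estimated correlation). Tubb3 differed by −0.40 and the vesicular glutamate transporter Slc17a7 by −0.80. Myc targets moved down with 29 of 35 negative and 0 passing either way (adjusted p = 0.0355, and adjusted p = 0.815 with an estimated correlation). Nuclear oxidative phosphorylation genes moved down with 74 of 80 negative (adjusted p = 0.0355, and adjusted p = 0.815 with an estimated correlation), although the 2 members that passed, Ndufa4l2 (3.01) and Cox6b2 (3.08), were higher. The lists that did not pass were Notch (adjusted p = 0.389), Wnt (0.316), glycolysis and hypoxia (0.568), unfolded protein response (0.448), DNA methylation and Polycomb (0.538), caudal patterning (0.568), medial cortex and hippocampus (0.538), sex-linked (0.498), ribosomal protein (0.448) and mitochondrial genome genes (0.532). Of their members 1 Notch, 2 Wnt and 1 glycolysis gene passed over all genes, and 1 Notch, 4 Wnt, 1 glycolysis, 6 caudal and 3 medial genes when adjusted over the list alone. The mean differed in sign from the test for unfolded protein response, DNA methylation and caudal genes (tested down, means 0.03, 0.04 and 0.05), the median for medial genes (tested up, median −0.01), and both for ribosomal protein genes (tested down, median 0.02 and mean 0.01).

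Radial glia-like cells were compared to ask how progenitors, in which Nestin-Cre is active, differed within the class. In 2774 cells, 0 of 13475 genes passed in edgeR (600 at an unadjusted p under 0.05, 673.75 expected by chance), and DESeq2 called 8. The genes with the smallest p were Anxa1 (93 against 1 count, ratio 87.5, 15.3 to 3494, adjusted p = 0.250), the receptor tyrosine kinase Alk (1.27 ± 0.163, adjusted p = 0.275) and Lbhd2 (67 against 1 count, ratio 63.1, 10.9 to 2527, adjusted p = 0.511). With 1 library left out, the log2 fold change ran from 5.70 to 8.29 for Anxa1, 1.14 to 1.39 for Alk and 5.34 to 7.97 for Lbhd2. Over all alternatives, edgeR fits and DESeq2, the adjusted p ran from 5.62e-10 to 0.409, 9.64e-09 to 0.409 and 6.81e-08 to 0.843. Anxa1 and Lbhd2 are among 12 genes chosen for clusters 10 and 12. Cells with 10 or more of the chosen genes held 49.0% and 59.4% of the counts of these 12 in i4F-Nes radial glia-like cells. Such cells numbered 107 and 37 in i4F-Nes and 60 and 16 in CTR. Pou5f1 (0.74), Sox2 (−0.09), Klf4 (−0.31), Myc (−0.97), Mki67 (0.39) and Pax6 (0.03) did not pass. Of the lists, 8 passed with 0 members passing either way. Moving up were G2 and M phase genes (38 of 54 positive, adjusted p = 0.00700, and adjusted p = 0.865 with an estimated correlation) and glycolysis and hypoxia genes (21 of 29, adjusted p = 0.00656, and adjusted p = 0.510 with an estimated correlation). Moving down were Myc targets (33 of 35 negative, adjusted p = 2.83e-06) and nuclear oxidative phosphorylation (74 of 79, 2.83e-06), ribosomal protein (73 of 81, 0.000199), rostral patterning (8 of 9, 0.000994), immediate early (20 of 25, 0.00171) and unfolded protein response genes (17 of 19, 0.00171). With an estimated correlation these 6 had an adjusted p = 0.510, 0.865, 0.865, 0.510, 0.817 and 0.510. The mix of clusters within the class was not held fixed. Cluster 19, led by Top2a, held 233 of 921 and 115 of 570 i4F-Nes against 146 of 770 and 81 of 513 CTR cells. Leaving out 1 library changed the count of genes to 48 (without i4F-Nes replicate 1), 14 (CTR replicate 1), 3 (i4F-Nes replicate 2) and 193 (CTR replicate 2), and left 4 lists without i4F-Nes replicate 1.

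Intermediate progenitor-like cells, the transit-amplifying cells between radial glia and neurons, held 2 genes that rose. Nrxn3, a presynaptic adhesion molecule (ENSMUSG00000066392, GRCm38 chromosome 12, 88722876 to 90334935), stood at 262 and 386 CPM in i4F-Nes against 61.9 and 67.1 CPM in CTR (2.33 ± 0.207, SE, n = 2 per group, adjusted p = 0.0422 in edgeR). Crabp2 (ENSMUSG00000004885, chromosome 3, 87948666 to 87953376) rose by 3.34 ± 0.277 (adjusted p = 0.0422) from 1.37 and 1.34 CPM in CTR. After thinning, 3.48% and 1.20% of i4F-Nes against 0.626% and 0.417% of CTR intermediate progenitor-like cells had a Crabp2 UMI (unthinned 7.68%, 4.19%, 2.16% and 1.34%; medians 14400, 12954, 15580 and 11682 UMIs). The immature neuron-like cells of the i4F-Nes libraries, as background, held it in 1.85% and 1.72% (unthinned 5.16% and 2.07%; medians 12647 and 10500 UMIs), so that in replicate 2 the share lay below the background. Crabp2 is a leading gene of cluster 12, where 67.4% and 56.4% of thinned cells held a UMI. Free RNA or misplaced cells of that cluster were not tested as the source of Crabp2 here. Krt8 was at least 123-fold higher (298 against 0 counts) without passing (adjusted p = 0.0545), and Lgals7 differed by 2.34 (adjusted p = 0.101). With 1 library left out, the log2 fold change of Krt8 ran from 9.57 to 10.8 and that of Lgals7 from 2.04 to 2.61. Over all alternatives, edgeR fits and DESeq2, the adjusted p ran from 3.03e-39 to 0.0554 for Krt8 and from 1.19e-15 to 0.328 for Lgals7. Eomes, the transcription factor that defines these cells (0.00), and Mki67 (0.75) did not pass. In each of the 3 clusters of the class more i4F-Nes than CTR cells held an Nrxn3 UMI after thinning. Without doublet removal 0 of the 2 genes passed (Nrxn3 2.30, adjusted p = 0.185, range over alternatives 2.88e-36 to 0.185; Crabp2 1.99, adjusted p = 1.00, range 9.13e-17 to 1.00). Of 13478 genes 329 had an unadjusted p under 0.05 (673.9 expected by chance), DESeq2 called 10, and leaving out i4F-Nes replicate 1, CTR replicate 1, i4F-Nes replicate 2 or CTR replicate 2 gave 16, 9, 10 and 43.

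**Figure D4:**
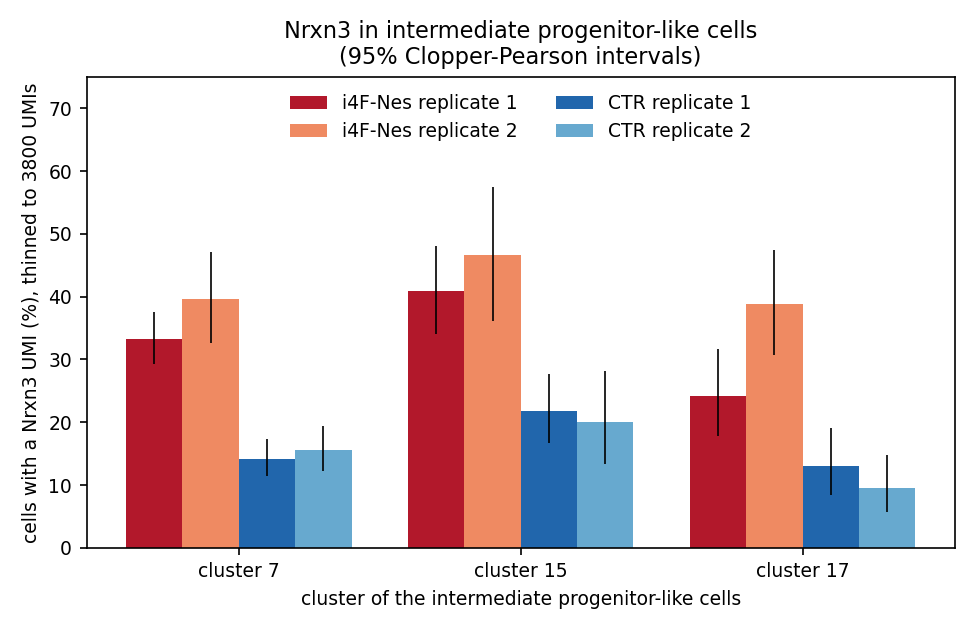
Bars show the percent of cells with an Nrxn3 UMI after thinning to 3800 UMIs, with exact 95% binomial intervals, in clusters 7, 15 and 17 of the intermediate progenitor-like class for each library. In cluster 7 the shares were 33.3% and 39.7% in i4F-Nes and 14.2% and 15.6% in CTR, in cluster 15 40.9% and 46.7% against 21.8% and 20%, and in cluster 17 24.2% and 38.8% against 13.1% and 9.55%.

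Of the gene lists 9 passed in intermediate progenitor-like cells, with 0 members passing over all genes. S phase genes moved up with 43 of 43 positive (adjusted p = 2.30e-13), as did G2 and M phase genes with 52 of 54 (adjusted p = 6.12e-12), glycolysis and hypoxia genes with 21 of 29 (adjusted p = 1.47e-05) and outer radial glia genes (adjusted p = 0.0359). With an estimated correlation each had an adjusted p = 0.808. Adjusted over the list alone, 1 glycolysis gene passed, and 0 of the other 8 lists. Ldha, which makes lactate, differed by 0.58, and Top2a by 0.70. The mix of clusters within the class was not held fixed. Cluster 17, led by Top2a, held 163 of 899 and 143 of 477 i4F-Nes against 171 of 971 and 183 of 748 CTR cells. Immediate early genes moved down with 22 of 24 negative (adjusted p = 0.000233), as did nuclear oxidative phosphorylation genes with 73 of 80 (adjusted p = 0.000179), unfolded protein response genes with 19 of 20 (adjusted p = 0.00521), medial cortex and hippocampus genes with 7 of 8 (adjusted p = 0.00856) and ribosomal protein genes with 62 of 81 (adjusted p = 0.0359). With an estimated correlation the adjusted p was 0.808, and 0.885 for ribosomal protein genes.

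Neuron-like classes were compared to ask whether the progeny of these progenitors differed. Fits with the replicate number as a block, a pairing that no label gives, called genes in immature, upper-layer and deep-layer neuron-like cells. Those calls are counted further below, and the fits in this part had no block. In 4223 immature neuron-like cells, 0 of 13182 genes passed in edgeR (267 at an unadjusted p under 0.05, 659.1 expected by chance), and DESeq2 called 9. The smallest p values were those of Ptprt, a receptor tyrosine phosphatase (1.24 ± 0.143, 183 and 192 against 71.8 and 87.5 CPM, adjusted p = 0.579) and Lgals7 (1.5 ± 0.215, adjusted p = 0.895). Lgals7 is a leading gene of clusters 10 and 12, whose free RNA or misplaced cells were not tested as its source here. Without CTR replicate 1 or CTR replicate 2 both passed (Ptprt adjusted p = 0.00146 and 0.00171, Lgals7 0.000123 and 0.00828), and Ptprt also without i4F-Nes replicate 2 (0.00135), with ranges over alternatives of 1.96e-11 to 1.00 and 2.65e-07 to 1.00. The lists of immediate early (21 of 24 negative, adjusted p = 8.26e-08), ribosomal protein (71 of 81, 2.68e-05), glycolysis (21 of 27, 0.000149), medial cortex and hippocampus (7 of 8, 0.000448) and nuclear oxidative phosphorylation genes (70 of 80, 0.0106) moved down. With an estimated correlation these 5 had an adjusted p = 0.590, 0.747, 0.590, 0.590 and 0.747, and 0 members passed over all genes or adjusted over the list alone. Leaving out CTR replicate 1, i4F-Nes replicate 2 or CTR replicate 2 gave 24, 9 and 23 genes, and leaving out i4F-Nes replicate 1, CTR replicate 1 or i4F-Nes replicate 2 gave 3, 9 and 9 lists.

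In 5657 upper-layer neuron-like cells, 0 of 14164 genes passed in edgeR (131 at an unadjusted p under 0.05, 708.2 expected by chance), and DESeq2 called 0. Deviations of same-numbered libraries correlated at 0.739 here, and genes did pass with the replicate number as a block. The smallest p values were those of the imprinted long noncoding RNA Meg3 (0.79 ± 0.131), the ion exchanger Slc24a2 (0.98 ± 0.17) and Cemip (1.61 ± 0.303), each with an adjusted p of 1.00. Cux2 (0.04), Bcl11b (−0.05) and Tbr1 (0.43) did not pass. Immediate early genes moved down with 21 of 26 negative (adjusted p = 2.35e-07, and adjusted p = 0.898 with an estimated correlation), Fos at −1.26 and Fosb at −1.30 without passing. Among the alternatives both passed without CTR replicate 2 (adjusted p = 1.39e-09 and 0.0433) and without a filter on low counts (adjusted p = 3.22e-08 and 0.00119; ranges over alternatives 1.39e-09 to 1.00 and 0.00119 to 1.00). Caudal patterning genes moved down with 7 of 9 negative (adjusted p = 0.00161), the orphan receptor Nr2f1 at −0.52 and the adhesion molecule Tenm3 at −0.45, and medial cortex and hippocampus genes with 6 of 7 (adjusted p = 0.00162). Both had an adjusted p = 0.848 with an estimated correlation. Ribosomal protein genes moved down with 67 of 81 negative (adjusted p = 0.0107, and adjusted p = 0.898 with an estimated correlation). The mix of the 3 clusters of the class, which was not held fixed, differed: cluster 6 held 305 of 1499 and 354 of 1137 i4F-Nes against 469 of 1208 and 660 of 1813 CTR cells. No member of these lists passed over all genes or adjusted over the list alone (0 of each list). Without CTR replicate 2, 122 genes passed, without i4F-Nes replicate 1, 4, and without i4F-Nes replicate 2, 1. Leaving out i4F-Nes replicate 2 or CTR replicate 2 gave 7 lists each.

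In 3655 deep-layer neuron-like cells, 0 of 13756 genes passed in edgeR (278 at an unadjusted p under 0.05, 687.8 expected by chance), and DESeq2 called 1. That correlation of same-numbered libraries was 0.734 in this class, where genes passed under the replicate block too. The smallest p values were those of the calcium-binding protein Calb2 (3.99 ± 0.565, 96 against 5 counts), Egfem1 (−0.92 ± 0.159), the cadherin Cdh4 (1.03 ± 0.185) and the transcription factor Bhlhe22 (−0.63 ± 0.122), each with an adjusted p of 0.991. Calb2 was also over 2-fold higher in cluster 12 than in immature neuron-like cells. Free RNA or misplaced cells of cluster 12 were not tested as the source of Calb2 here. Calb2 passed without CTR replicate 2 (adjusted p = 0.0182, range over alternatives 0.00259 to 1.00) and Cdh4 without CTR replicate 1 (adjusted p = 0.0158, range 0.0158 to 1.00). The list of nuclear oxidative phosphorylation genes moved down with 78 of 78 negative (adjusted p = 5.47e-13), as did ribosomal protein genes with 77 of 81 (2.41e-12), Myc targets with 32 of 35 (1.21e-05), glycolysis genes with 20 of 27 (0.00221), immediate early genes with 19 of 25 (0.00305) and unfolded protein response genes with 17 of 20 (0.00484). With an estimated correlation these 6 had an adjusted p = 0.517, 0.823, 0.517, 0.517, 0.838 and 0.517, and 0 members passed over all genes or adjusted over the list alone. The mix of the 2 clusters of the class was not held fixed: cluster 3 (median 12490 UMIs, against 19450 in cluster 8) held 618 and 525 i4F-Nes against 248 and 525 CTR cells, and cluster 8 held 521 and 237 against 499 and 482. Without CTR replicate 2, 91 genes passed, and 1 passed without CTR replicate 1 or i4F-Nes replicate 2.

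Interneuron-like cells, which enter the cortex from the ventral forebrain, were compared as well. Whether Nestin-Cre was active in their progenitors was not tested, so they are not a control without induction. In 884 cells, Kif26b, a kinesin family member (ENSMUSG00000026494, GRCm38 chromosome 1, 178529125 to 178939200), rose from 9.16 and 7.42 CPM in CTR to 34.1 and 69.5 CPM in i4F-Nes (2.60 ± 0.390, SE, n = 2 per group, adjusted p = 0.00799 in edgeR, 77 against 31 counts). It was the 1 gene called of 9490 (321 at an unadjusted p under 0.05, 474.5 expected by chance). Kif26b was also among the 10 leading genes of cluster 7, an intermediate progenitor-like cluster. RNA from such cells and doublets with them were not tested as the source of the Kif26b counts. Kif26b missed the threshold in DESeq2 (adjusted p = 0.0902), which called 0 genes, without doublet removal (1.56, adjusted p = 1.00), with the stricter cell filter (adjusted p = 0.131) and in thinned sums (adjusted p = 0.0611), and over its alternatives the adjusted p ran from 1.14e-10 to 1.00. The proprotein convertase Pcsk2 (1.22, adjusted p = 0.148) and the serotonin receptor Htr3a (−2.24, 10 against 106 counts, adjusted p = 0.182) did not pass. Pcsk2 passed without CTR replicate 1 (0.0156) or CTR replicate 2 (0.0239; range over alternatives 5.53e-05 to 0.722), and Htr3a without i4F-Nes replicate 1 (0.0190), i4F-Nes replicate 2 (0.0392) or CTR replicate 2 (0.000683; range 0.000103 to 1.00). Neuronal differentiation and synapse genes moved up with 27 of 34 positive (adjusted p = 0.00297), Rbfox1 at 0.69, and ribosomal protein genes down with 73 of 81 negative (adjusted p = 0.00297). Both had an adjusted p = 0.924 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Leaving out i4F-Nes replicate 1, CTR replicate 1, i4F-Nes replicate 2 or CTR replicate 2 gave 125, 24, 16 and 48 genes and 1, 5, 6 and 6 lists.

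Whether radial glia-like and upper-layer neuron-like cells responded differently was tested as an interaction. Of 15168 genes 0 passed in edgeR (747 at an unadjusted p under 0.05, 758.4 expected by chance), and DESeq2 called 1. Nrxn3 had a response lower by −1.31 ± 0.161 (SE) in upper-layer neuron-like than in radial glia-like cells and Fstl5, a follistatin-like protein, by −1.02 ± 0.131, both with an adjusted p of 0.0573. Without i4F-Nes replicate 1, 205 genes passed, without i4F-Nes replicate 2, 18, and without CTR replicate 2, 6. Responses of other pairs of classes were not tested against each other.

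The balance of neuron types was the last question. Upper-layer neuron-like cells made up 56.8% (54.9 to 58.7) and 59.9% (57.6 to 62.1) of upper- and deep-layer neuron-like cells in i4F-Nes and 61.8% (59.6 to 64.0) and 64.3% (62.5 to 66.1) in CTR, means of 58.3% ± 2.16 and 63.0% ± 1.77 (SD, n = 2, exact permutation p = 0.333, two-sided, the smallest p that 6 splits allow). The difference of −4.69 percentage points turned to 2.44 without doublet removal, 6.28 at resolution 2.0 and 0.787 with clusters 1 and 18 added. The ratio of neuron-like to progenitor-like cells was 2.14 and 2.37 in i4F-Nes and 1.87 and 3.09 in CTR (2.25 ± 0.160 against 2.48 ± 0.860, n = 2, exact permutation p = 1, two-sided). Their difference of −0.228 became −0.114 without i4F-Nes replicate 1, −0.836 without CTR replicate 1 and 0.381 without CTR replicate 2. The ratio covers the named classes only. Cells of the numbered clusters entered neither side, among them clusters 10 and 12 with 12.9% of i4F-Nes and 0.00827% of CTR cells.

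Cycling was read from UMIs of Mki67 or Top2a in thinned cells. Of radial glia-like cells, 56.2% (52.7 to 59.6) and 57.4% (52.6 to 62.1) in i4F-Nes and 50.4% (46.6 to 54.1) and 56.7% (51.6 to 61.6) in CTR held such a UMI, means of 56.8% ± 0.884 and 53.5% ± 4.46 (SD, n = 2, exact permutation p = 0.667, two-sided). Unthinned shares were 65.6% and 66.1% against 66.8% and 65.7%, at medians of 14475, 12144, 16905 and 12419 UMIs, and the thinning left out 109, 138, 73 and 123 cells. In upper-layer neuron-like cells, as background, the thinned shares were 1.42% and 2.72% against 1.25% and 1.18%, at medians of 15078, 14621, 16732 and 13991 UMIs. The difference of 3.27 percentage points became −0.362 without thinning, 0.116 without CTR replicate 1 and 6.42 without CTR replicate 2. Of intermediate progenitor-like cells, without a test, 18.3% (15.8 to 21) and 34.9% (30.4 to 39.7) in i4F-Nes and 14.1% (11.9 to 16.5) and 20.8% (17.9 to 24.0) in CTR held such a UMI, unthinned 24.4% and 39.4% against 22% and 27.8%, at medians of 14400, 12954, 15580 and 11682 UMIs.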

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

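The tests of neighbouring tissue, of embryo sex and of cells of clusters 10 and 12 among the intermediate progenitor-like cells were chosen after the results they measure were seen, and the test of the genotype was split by cluster at that point with its bounds kept.

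Barcodes left out of the comparisons by the cell filters or as doublets carried genes chosen for clusters 10 and 12, at shares above CTR. With 30 genes chosen in the other i4F-Nes library, 5.77% of the left-out barcodes of i4F-Nes replicate 1 and 2.89% of those of replicate 2 carried 15 or more genes of cluster 10, against 0 of 1896 and 0 of 1520 in CTR, which allows up to 0.158% and 0.197%. For cluster 12 the shares were 9.17% in i4F-Nes replicate 1 against at most 4.32% in CTR, and 2.13% in replicate 2 against at most 0.0527%. The cluster 12 genes used for replicate 1 also marked 1.39% of the kept cells of CTR replicate 1, 0 of them in clusters 10 or 12. They thus do not single out cells of cluster 12. A test of the difference between upper-layer neuron-like and radial glia-like cells set apart 4 gene lists. The response was higher in upper-layer neuron-like cells for Myc targets (adjusted p = 2.73e-05, and adjusted p = 0.789 with an estimated correlation) and nuclear oxidative phosphorylation genes (adjusted p = 0.00475, and adjusted p = 0.886 with an estimated correlation). It was lower for glycolysis and hypoxia genes (adjusted p = 2.03e-05, and adjusted p = 0.773 with an estimated correlation) and mitochondrial genome genes (adjusted p = 0.0422, and adjusted p = 0.886 with an estimated correlation).

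Clusters 10 and 12 were found in both i4F-Nes libraries and nearly absent from CTR. Doublets of other cell types are argued against by at least 47 genes over 2-fold above every other cluster of the same library, and sex by the female CTR library, which held 0% of its cells in them. Cells of a neighbouring tissue stay open: 50% of the 8 surface ectoderm markers (Krt14, Krt10, Dsp and Perp, at most 48.0 CPM) were detected in 10% or more of cluster 10 cells. Perp is also a listed p53 target that was over 2-fold higher there than in radial glia-like cells. Of 8 neural crest and Schwann cell markers, Erbb3, Sox10 and Prrx1 were detected in 10% or more of cluster 10 cells. Cortical markers were detected there too (unthinned), Pax6 in 78.2% and 77.0% of cells and Bcl11b in 71.3% and 56.5%. Of the caudal patterning list, Emx2 was in 85.1% and 72.2% and Emx1 in 34.2% and 24.2%. Against radial glia-like cells, Bcl11b was over 2-fold higher and Pax6 and Emx1 over 2-fold lower, so these values do not decide. The i4F-Nes genotype stays open as well, since the clusters were defined on both i4F-Nes libraries and the genes chosen from them, so that finding the cells again decides nothing: genes chosen in 1 library marked at least 6.71% of the cells of the other for cluster 10, against at most 0.0165% in CTR. For cluster 12 the genes chosen in i4F-Nes replicate 1 marked 4.59% of replicate 2 and at most 0.0662% of CTR, while those chosen in replicate 2 marked 6.21% of replicate 1 and 1.39% of CTR replicate 1, over the bound set beforehand (84 cells, none of them in clusters 10 or 12, median 29904 UMIs, and 11 of the 30 genes in at least 20% of CTR neuron-like cells).

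Of the genes chosen for clusters 10 and 12, the 12 under 0.5 CPM over all CTR cells, such as Krt8 and Anxa1, were also seen in other classes of the i4F-Nes libraries, with 54.1 and 31.2 counts per 100 intermediate progenitor-like cells, and their low level in CTR follows from that choice. Free RNA as the whole source is argued against in replicate 2 by a 12.1-fold spread between classes. Counts per 100 cells were 31.2 (26.4 to 36.7) in intermediate progenitor-like and 2.59 (1.45 to 4.27) in immature neuron-like cells. The 5.29-fold spread in i4F-Nes replicate 1 does not decide beyond counting error. It set 54.8 (31.9 to 87.8) in microglia- or macrophage-like against 10.4 (5.67 to 17.4) in interneuron-like cells. Microglia- or macrophage-like cells held such counts in CTR too (31.0 and 50 per 100 cells). Outside cells with 10 or more of the chosen genes, the other classes of replicate 1 held 10 to 19.0 per 100 cells. Cells of clusters 10 and 12 placed among the intermediate progenitor-like cells stay open: cells with 10 or more of the genes chosen for either cluster held 79.4% and 84.6% of the counts there, and 75.5% and 82.6% when the counted genes were left out of the choice, while making up 35.4% and 15.3% of the class. That criterion was met by 34.4% and 10.2% of CTR cells of the class too, so it does not single out such cells. Over all classes such cells held 47.2% and 56.1% of the counts, between the bounds of 20% and 50% in 1 library, and free RNA as a part of the source stays open.

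Nrxn3 was higher in intermediate progenitor-like cells of both i4F-Nes libraries. RNA from interneurons is argued against by 6 other interneuron genes, whose median excess was −0.0187 of that expected from the Nrxn3 excess. Cells of clusters 10 and 12 placed in the class are argued against as the source of the Nrxn3 excess because 102% of the excess was left without cells that held 10 or more of their genes, a criterion that CTR cells met too. Doublets stay open. The log2 fold change was 2.33 without the called doublets and 2.30 with them, where the call ended (adjusted p = 0.185 in edgeR). The classes were rebuilt for the second fit, and doublets that were not called stayed in both, so the 2 values cannot decide. The i4F-Nes genotype itself stays open and was not tested.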

How the results depend on the processing

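The alternatives without clusters 10 and 12, without clusters 9 and 18, with clusters 1 and 18, and with shares over other denominators were chosen after the results were seen. The cause was not tested for any change below, except that fewer cells or genes entered some fits by construction. With 1 library left out, 1 group had a single library, which was assumed to vary like the other group. With 2 libraries per group the exact permutation tests could not pass, and replicate 1 of both groups was deeper than replicate 2.

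No filter on low counts moved the genes called to 802 over all kept cells, 87 in radial glia-like, 60 in intermediate progenitor-like, 33 in immature neuron-like, 95 in upper-layer, 2 in deep-layer and 43 in interneuron-like cells, and 82 for the difference of response. DESeq2 called 1173, 8, 10, 9, 0, 1 and 0 in that order of classes, and 1 for the difference of response. Without doublet removal 616 genes were called over all kept cells and 0 in intermediate progenitor-like cells. Thinned sums gave 4 genes and centring per library 5 in intermediate progenitor-like cells, and the stricter filter 0 in interneuron-like cells. Without clusters 10 and 12, 0 genes were called over all kept cells by edgeR, with 337 at an unadjusted p under 0.05.

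Leaving out 1 library gave 547 to 779 genes over all kept cells, 3 to 193 in radial glia-like, 9 to 43 in intermediate progenitor-like, 0 to 24 in immature neuron-like, 0 to 122 in upper-layer, 0 to 91 in deep-layer and 16 to 125 in interneuron-like cells, and 0 to 205 for the difference of response. It gave 0 to 1 of the factors and 2 to 3 classes by share. Gene lists ran from 7 to 13 over all kept cells, 4 to 9 in radial glia-like, 6 to 9 in intermediate progenitor-like, 3 to 9 in immature neuron-like, 4 to 7 in upper-layer, 4 to 7 in deep-layer and 1 to 6 in interneuron-like cells. The upper-layer share ran from −6.22 to −3.17 percentage points, the ratio of neuron-like to progenitor-like cells from −0.836 to 0.381 and the cycling share from 0.116 to 6.42.

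With an estimated correlation 0 gene lists passed in each of the 7 comparisons, and with fry 1 over all kept cells and 0 in each class. By share, 4 classes passed at resolution 2.0, 6 of 19 with expression centred per library, immature neuron-like cells among them, and 0 over cells outside clusters 10 and 12. The upper-layer share turned to 2.44 percentage points without doublet removal, 6.28 at resolution 2.0 and 0.787 with clusters 1 and 18. The ratio turned to 0.0201 with the stricter filter and the cycling share to −0.362 without thinning. Centring gave no count of genes for immature neuron-like and upper-layer cells, and no value for the difference of response, the upper-layer share and the ratio.

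The samples share only a number, so pairing rests on no label. Deviations of same-numbered libraries correlated across genes at 0.490 over all kept cells and between 0.221 and 0.739 in the classes, with 2 pairs. With the replicate number as a block, 1286 genes were called over all kept cells, 15 in radial glia-like, 72 in intermediate progenitor-like, 169 in immature neuron-like, 205 in upper-layer, 542 in deep-layer and 117 in interneuron-like cells. Under the block 0 classes passed by share (2 at an unadjusted p under 0.05 in edgeR), 10 gene lists passed in immature neuron-like cells, and 1 factor, Pou5f1, passed. Over all kept cells Egr1 and Hopx missed the threshold under the block. The difference of response had the library as a block already.

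Among 259 genes named per comparison, 2954 of 3334 pairs of gene and alternative kept direction and side of the threshold, 320 passed newly, 39 passed no more and 21 turned sign. Over all kept cells and with 1 library left out, Sox2 ran from −0.27 (without CTR replicate 2) to 0.53, with −0.01 without i4F-Nes replicate 1. Klf4 ran from −0.72 to 0.32, Myc from −0.68 to 0.10 and Pax6 from −0.36 to 0.33, each turning sign without CTR replicate 1, and Pax6 stood at 0.01 without i4F-Nes replicate 1. Bcl11b ran from −0.32 to 0.024, turning without i4F-Nes replicate 2. Without clusters 10 and 12, Sox2 turned to −0.093, Bcl11b to 0.025, Tbr1 to 0.19, Hopx to −0.32, Itgb5 to −0.58, Egr2 to −1.62 and Egr1 to −0.25. With 1 library left out, Rpl35 ran from −0.76 to 0.014 in radial glia-like cells and from −0.60 to 0.034 in intermediate progenitor-like cells, and Dmrt3 from −1.84 to 0.26 in intermediate progenitor-like and from −3.07 to 0.14 in upper-layer neuron-like cells, each turning sign without CTR replicate 1. With the stricter filter Xbp1 turned to 0.067 and Pdia4 to 0.063 in deep-layer neuron-like cells, and without doublet removal Meis2 to −0.36 in interneuron-like cells.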

Other observations

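Clusters 10 and 12 also differed from the reference classes of the same libraries in genes outside their leading ones, described over 2-fold in both i4F-Nes libraries and chosen after the values were seen. In cluster 10, 13 of 25 immediate early genes were higher than in radial glia-like cells, Fos at 563 and 589.8 CPM against 78.2 and 39.4 CPM and Egr1 at 244 and 247 against 11 CPM in both libraries, and 5 of 21 p53 targets were higher. Sox10, a transcription factor of the oligodendrocyte and neural crest lineages, stood at 39.4 and 62.4 CPM. Of 34 Myc targets 0 were higher, and Klf4 (8.02 and 8.86 CPM) and Myc (8.02 and 10.6 CPM) were low. In cluster 12, 5 of 25 glycolysis and hypoxia genes were higher than in immature neuron-like cells, among them Ldha and the glucose transporter Slc2a3, and Mki67 was at 7.50 and 7.97 CPM.

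After thinning, 57.5% and 41.2% of cluster 10 cells (unthinned 84.5% and 61.9%) and 3.20% and 3.04% of cluster 12 cells (unthinned 17.3% and 11.4%) had a UMI of Mki67 or Top2a. In upper-layer neuron-like cells of the same libraries the shares were 1.42% and 2.72% (unthinned 6.14% and 6.51%). Median depths were 34701 and 24264 UMIs in cluster 10, 22370 and 15436 in cluster 12, and 15078 and 14621 in upper-layer neuron-like cells.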
